A study of Homo sapiens with 6 samples.

How the data were processed

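Gene expression was measured on Affymetrix microarrays in SNU-398, an established human hepatocellular carcinoma cell line. Total RNA of 6 cultures was labelled and hybridized, 3 with a scrambled control short hairpin RNA (shRNA) and 3 with an shRNA against SALL4, and the labels call the 3 of each group biological replicates. The deposited table holds intensity values on a linear scale for 32319 probe sets, groups of probes summarised into 1 value each. RMA, a method that corrects background, normalizes arrays and summarises probes, is named in the submitters' processing notes; its version and the steps after it are not given in the sources used here. RMA ends on a log2 scale, whereas the deposited intensities are linear and never below 10. Between 15.5% and 16.9% of the values of each array lie exactly at 10, and the array medians lie between 47.85 and 51.69, so a floor was set and the distributions are similar but not identical. A gene at the floor has only an upper bound, and changes of dim genes are understated.

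Log2 of each deposited intensity was taken here, because the planned test had assumed log2 values. Probe sets were named through the platform annotation supplied with the series: 19158 have 1 gene symbol, 1388 have several and 11773 are not listed there. Symbols were updated through the Entrez identifier, which matched for 19128 probe sets. For each of the resulting 18404 genes the probe set with the highest mean over the 6 arrays was used, which mattered for 637 genes with more than 1 probe set. No genomic coordinates are given, since the build behind the annotation is not named. No per-sample column was left unused.

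The comparison, SALL4 shRNA minus scrambled shRNA, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated and two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit fixed before the data were examined used all 18404 genes with no filter. In that fit 552 genes lie at the floor on all 6 arrays and have a variance of 0. The prior degrees of freedom, with which limma shares the spread between genes, were 1.09 with these genes and 4.97 without them. A second fit, also planned, kept the 13711 genes with a mean log2 intensity of at least 5 (an intensity of about 32) in at least 1 group, and its prior degrees of freedom were 8.01. It is called the filtered fit; leading with it was decided after both results had been seen, and its counts of genes are given with the unfiltered ones. Rose, fell and passed refer to the filtered fit unless another is named. Means are of the deposited intensities with the standard deviation (SD) over 3 arrays, fold changes are on the log2 scale, and their standard errors (SE) come from the filtered fit.

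On simulated arrays with the real gene means and spreads and the floor, with 200 changed genes, the unfiltered fit of 18404 genes recovered 26% of genes shifted by 1 and 72% of those shifted by 2 on the log2 scale, with 6 false calls among 74. The filtered fit, of 13647 simulated genes, recovered 48% and 94%, with 8 false calls among 120. The changed genes were drawn only from brighter genes, so recovery of dim genes was not simulated. The prior degrees of freedom were 0.993 and 2.97 in the simulation, so the simulated filtered fit differs from the real one, and a low prior alone does not rule out calls. The list test, run on 18404 genes, found a simulated change of -0.3 in the replication genes. The simulated genes were not correlated, so this does not test its rate of false calls on real arrays.

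Before the data were examined, 33 gene lists were fixed, including markers of blood cells, endothelium, fibroblasts and cholangiocytes. They were tested with limma's camera on all 18404 genes with a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation was the first alternative test. Limma's fry, the second, asks whether the genes of a list move on balance one way and does not compare them with other genes. Medians of lists were also placed among 10000 random lists matched on mean expression. The genes named are SALL4, the 12 largest rises and 12 largest falls among genes that passed with non-overlapping groups, up to 4 members of each list that passed (or up to 2 members as values where none did), and a few genes fixed by name. Clone names, microRNAs and SNOR symbols were left out of the 12 and 12. The rule was written for the unfiltered fit, where no rise, fall or list member would have been named as passing. It was therefore applied to the filtered fit. Some of the genes fixed by name or in lists are not reported here; list sizes count measured genes, or those in the filtered fit where calls of single genes are counted. Counts adjusted over the list alone are from the filtered fit unless the unfiltered one is named. The number of arrays limits the precision, and 3 against 3 arrays cannot give an exact permutation p under 0.1.

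Replicate numbers are shared between the groups, but the labels do not say that a number marks a shared day or batch. Deviations of same-numbered arrays from their group means correlated at -0.0065, -0.079 and -0.036, so the numbers were not taken to pair the samples. The alternatives were a filter at log2 5 or 7, eBayes with trend and robust settings, median centring, quantile normalization, the mean of a gene's probe sets, array weights, the replicate block, all probe sets, limma's treat and leaving out each array. These were planned for the unfiltered fit; applying them to the filtered fit was decided after seeing the data. Other settings were also added after seeing the data: leaving out the genes at the floor on all arrays, and leaving out scrambled replicate 3 and knockdown replicate 2 together.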

Results

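The series profiled SNU-398 hepatocellular carcinoma cells on 6 arrays, 3 from cultures with a scrambled shRNA and 3 from cultures with an shRNA against SALL4, a zinc finger transcription factor of embryonic stem cells and fetal liver. The design gives 1 comparison: which transcripts differ between cultures with the SALL4 shRNA and with the scrambled shRNA. The labels name no second SALL4 shRNA and no rescue. Other effects of the hairpin therefore cannot be told apart from those of lower SALL4. The arrays had median intensities between 47.85 and 51.69. The first principal component, 29.3% of the variance, separated the groups, with scrambled arrays from -35.8 to -29 and knockdown arrays from 22.2 to 49.3. The second, 21.3% of the variance, set scrambled replicate 3 (-54.9) and knockdown replicate 2 (-23.4) apart from the others (17.2 to 22.5).

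SALL4 itself was lower in each of the 3 knockdown arrays than in any scrambled array. Its intensity was 294 ± 36.8 (SD, n = 3) with the scrambled shRNA and 119 ± 1.67 (SD, n = 3) with the SALL4 shRNA. The difference of the log2 means corresponds to 40.6% of the control intensity on this array. The individual values were 283.49, 264.25 and 335.43 against 120.65, 118.73 and 117.33. The log2 fold change was -1.30 ± 0.18 (SE), with a limma adjusted p of 0.0112 in the filtered fit and 0.0946 in the unfiltered fit. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. SALL4 was measured by 1 probe set, whose place in the transcript is not given in the sources used here. Without scrambled replicate 3 and knockdown replicate 2 together the filtered limma fit gave an adjusted p of 0.0737.

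In the filtered fit 220 of 13711 genes passed, and 145 of them fell and 75 rose with SALL4 knockdown. Each of the 220 changed by at least 0.79 on the log2 scale, so all were past 1.5-fold, and in all 220 the groups did not overlap. Non-overlapping groups were seen in 22.4% of the genes of this fit, where chance alone gives 10% for genes chosen without the labels. The filter behind this fit used the real group means and admits genes bright in only 1 group, so the 10% is not an exact reference. In the unfiltered fit, which was the planned main fit, 0 of 18404 genes passed at any fold. There limma gave 2864 genes an unadjusted p under 0.05, and the lowest adjusted p was 0.0805. Limma with trend and robust settings on the same genes called 58, and leaving out only the 552 genes at the floor on all arrays gave 40. The count of 220 was also lower without any 1 array: it was 39, 45 and 79 without scrambled replicate 1, 2 or 3, and 103, 61 and 103 without knockdown replicate 1, 2 or 3. It was 15 without scrambled replicate 3 and knockdown replicate 2 together. Fewer arrays leave fewer degrees of freedom, so these counts do not show that particular arrays carried the calls. A filtered fit of all probe sets, which added those without a single gene name and the further probe sets of genes with several, called 10 of 20316. Among the 10, 1 higher and 5 lower probe sets had no single gene name, so most of the 220 calls were lost there.

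**Figure D1:**
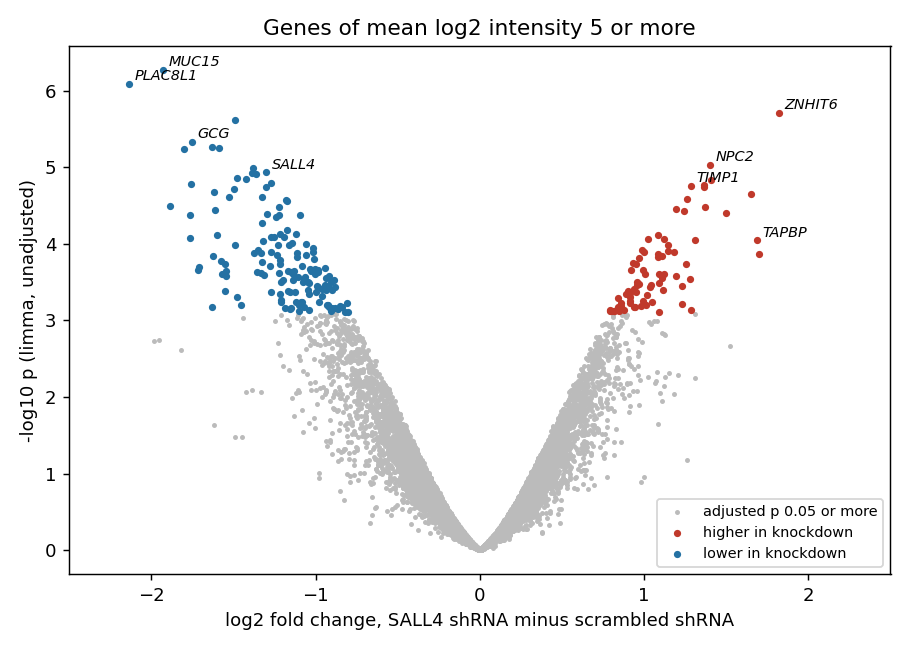
Log2 fold change (SALL4 shRNA minus scrambled shRNA, x axis) against -log10 of the unadjusted limma p (y axis) for the 13711 genes of the filtered fit; each point is a gene. The 75 genes higher in the knockdown (red) and 145 lower (blue) at an adjusted p under 0.05 include SALL4 at -1.30.

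The 12 named falls ranged from 4.39-fold to 3.05-fold. PLAC8L1 fell from 213 ± 33 to 49.4 ± 14.6 (SD, n = 3 each), a log2 change of -2.14 ± 0.23 (SE). MUC15, a membrane mucin, fell from 138 ± 18.6 to 36.4 ± 6.31, a log2 change of -1.93 ± 0.20. Both had a limma adjusted p of 0.00554 in the filtered fit. GCG, which encodes the precursor of glucagon, fell from 745 ± 130 to 224 ± 55.9, and PRRX1, a mesenchymal homeobox factor, from 242 ± 74.9 to 67.8 ± 11. LIFR, the receptor for leukaemia inhibitory factor, fell by 1.63 on the log2 scale with widely spread knockdown arrays (112 ± 70.8, adjusted p 0.046). TRAPPC13, a subunit of a vesicle tethering complex, fell by 1.63 by its brighter probe set. The mean of its 2 probe sets gave -0.77 with an adjusted p of 0.0539. B3GALT1, a galactosyltransferase gene (-1.71), NEMP2 (-1.89), ERI2 (-1.71), the small Cajal body RNA SCARNA10 (-1.62), FAM133A (-1.62) and RERGL (-1.61) made up the rest of the 12. For NEMP2 the mean of its 2 probe sets gave -1.33 with a limma adjusted p of 0.0118.

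The 12 named rises ranged from 3.54-fold to 2.44-fold. ZNHIT6, an assembly factor of box C/D small nucleolar ribonucleoproteins, rose from 184 ± 43.3 to 646 ± 94.1 (SD, n = 3 each), a log2 change of 1.82 ± 0.21 (SE) with a limma adjusted p of 0.00824. TAPBP, the peptide-loading chaperone tapasin of antigen presentation, rose by 1.69 ± 0.29, and the mean of its 3 probe sets by 1.08. TIMP1, a secreted inhibitor of metalloproteinases, rose from 873 ± 122 to 2122 ± 149. NPC2, a lysosomal cholesterol carrier, rose from 665 ± 71.7 to 1765 ± 242. Also among the 12 were TMBIM1 (1.65), the early endosomal GTPase gene RAB5B (1.37) and the RAB11 effector gene RAB11FIP4 (1.28). The general transcription factor gene GTF2B (1.36), the spliceosomal gene PRPF38A (2.83-fold) and the zinc finger gene ZNF799 (1.31) rose too, as did WDR47 (1.40) and LZIC (1.37). In the unfiltered limma fit the adjusted p of the 12 rises and 12 falls lay between 0.0946 and 0.2244. Of these 24 genes, 14, 17 and 21 passed the filtered fit without scrambled replicate 1, 2 or 3, and 19, 17 and 21 without knockdown replicate 1, 2 or 3. Without scrambled replicate 3 and knockdown replicate 2 together 6 passed.

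**Figure D2:**
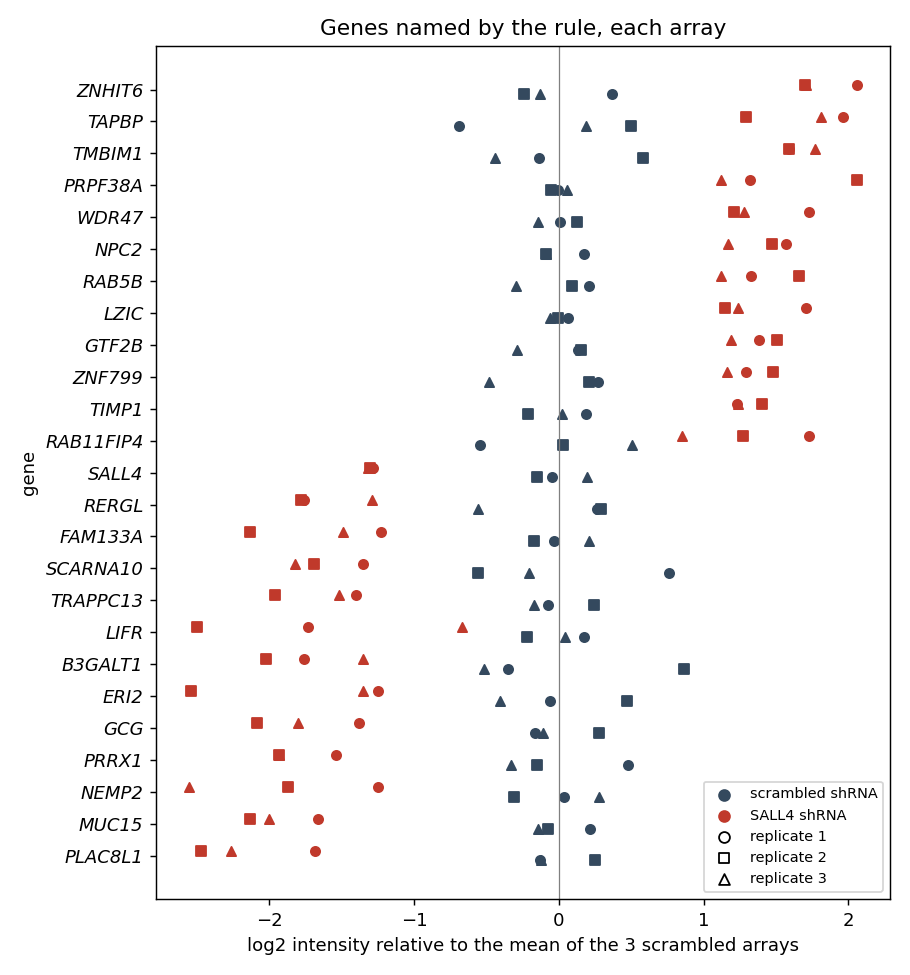
Log2 intensity of each array relative to the mean of the 3 scrambled arrays (x axis) for SALL4 and the 24 named rises and falls (y axis); dark points are scrambled and red points knockdown arrays, and the shape gives the replicate. For each gene the 3 knockdown arrays lie on one side of the 3 scrambled arrays.

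Genes of DNA replication were lower in the knockdown as a list, by small amounts. Of 38 genes of G1/S and DNA replication, 30 had a negative change and 8 a positive one, with a median log2 change of -0.28, and camera with the preset correlation gave an adjusted p of 0.000171. With an estimated correlation the adjusted p was 0.39 (unadjusted p = 0.024). In limma 0 of the 38 passed on their own, with 7 at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone (0 in the unfiltered fit). CDC6, a replication licensing factor, was at 940 ± 92.2 and 514 ± 91.1 (SD, n = 3 each), a log2 change of -0.88 ± 0.20 (SE) with a limma adjusted p of 0.0504. The cyclin gene CCNE1 was at -0.63 ± 0.34.

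Ribosomal protein genes were also lower as a list. Of 64 such genes, 51 had a negative change and 13 a positive one, with a median of -0.17 and a camera adjusted p of 1.95e-05 (adjusted p = 0.34 with an estimated correlation, unadjusted p = 0.01). RPL32 (-1.12 ± 0.23, SE) and RPL13 (-0.90 ± 0.20) fell and 59 of the 61 in the filtered fit did not pass, while 5 fell when adjusted over the list alone. In the unfiltered fit 0 passed over the list alone. For RPL13 the mean of its 3 probe sets gave -0.40 with an adjusted p of 0.402. Of the 6 fits without 1 array, RPL32 passed only without scrambled replicate 2 and RPL13 only without knockdown replicate 2. These genes have many near-identical pseudogene copies that can share signal with their probes, so single values are uncertain. Relative to the scrambled mean, the mean of the list was -0.248, -0.212 and -0.238 in the knockdown arrays and 0.0172, 0.0419 and -0.0591 in the scrambled arrays.

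Genes of G2/M and mitosis were lower as a list, but the list passed only in part of the fits. Of 35 genes, 27 had a negative and 8 a positive change, with a median of -0.22 and a camera adjusted p of 0.0412 (adjusted p = 0.71 with an estimated correlation). In limma 0 passed, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05; in the unfiltered fit 1 passed over the list alone. NUF2, a kinetochore gene, was at 0.83 ± 0.24 (SE) and HMMR, a spindle gene, at -0.61 ± 0.25. Without knockdown replicate 2 the list's adjusted p was 0.367, without scrambled replicate 1 it was 0.194 and without scrambled replicate 2 it was 0.163. In the filtered fit it was 0.123.

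**Figure D3:**
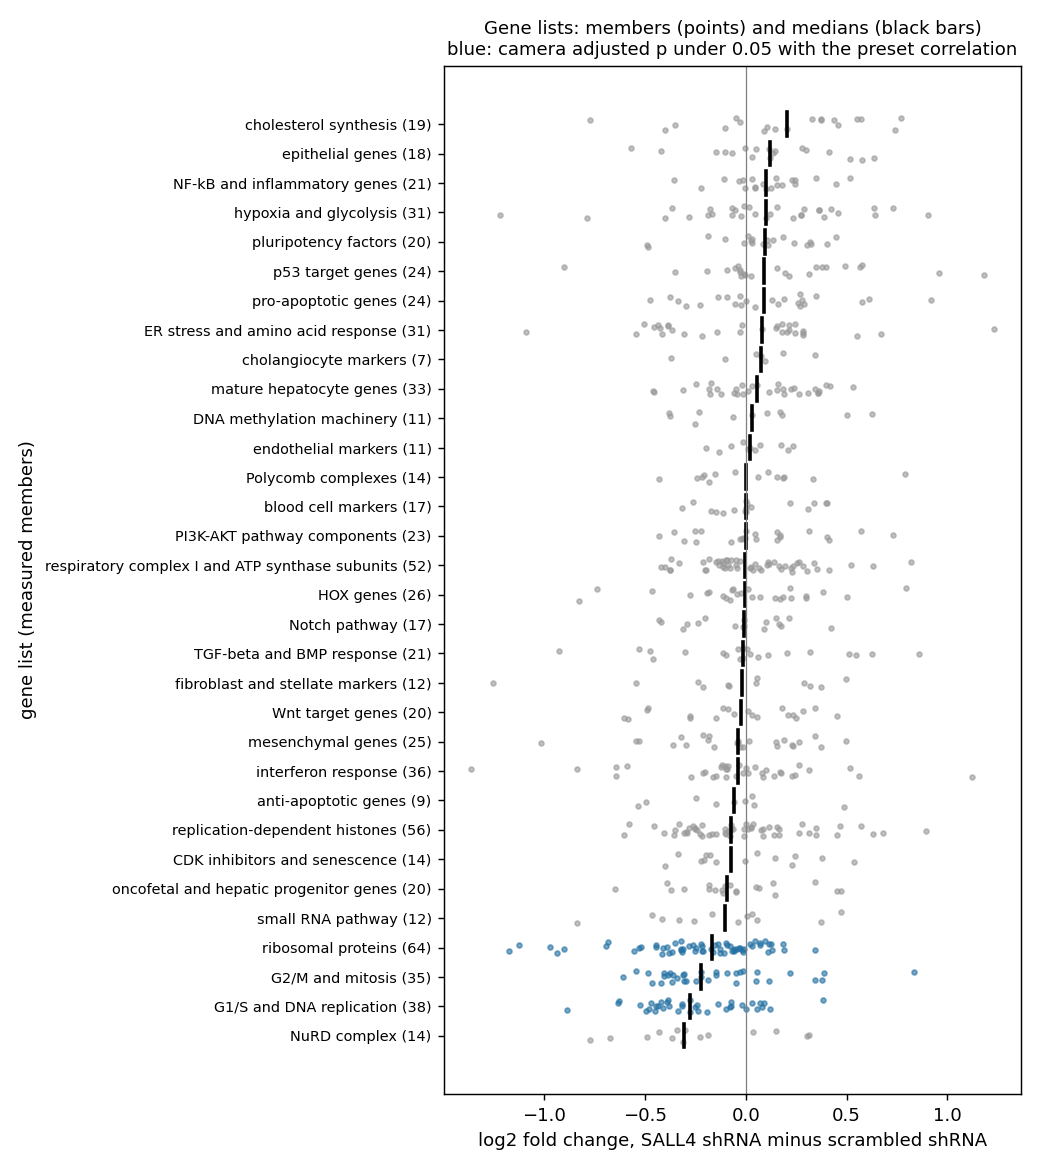
Log2 fold changes (SALL4 shRNA minus scrambled shRNA, x axis) of the measured members (points) of the fixed gene lists (y axis, number of members in brackets), with each list's median as a black bar; the list of ZNF symbols is left out for its size. The 3 lists in blue, replication, mitosis and ribosomal proteins, had a camera adjusted p under 0.05 with the preset correlation, and their medians lie at -0.28, -0.22 and -0.17.

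The other 30 lists did not pass camera, with adjusted p values from 0.115 to 0.933. The 14 genes of the NuRD complex, a histone deacetylase complex that SALL4 is known to bind, had a median of -0.31 and an adjusted p of 0.115 (0.6 with an estimated correlation). Without scrambled replicate 3 and knockdown replicate 2 together its adjusted p was 0.0353, and 0.0185 in the filtered fit, where leaving out knockdown replicate 2 alone gave 0.0414 and leaving out no array 0.123. In limma 0 of them passed over all genes, 3 had an unadjusted p under 0.05, and 1 fell when adjusted over the list alone (4 passed in the unfiltered fit). HDAC1, a deacetylase of the complex, was at 1304 ± 152 and 763 ± 94.1 (SD, n = 3 each), a log2 change of -0.77 ± 0.19 (SE) with a limma adjusted p of 0.0642, and the histone chaperone gene RBBP4 was at -0.67 ± 0.26. The 19 cholesterol synthesis genes had a median of 0.20 and an adjusted p of 0.115. Among them 0 passed over all genes and 6 had an unadjusted p under 0.05, while 3 rose and 1 fell when adjusted over the list alone (3 passed in the unfiltered fit). SC5D was at 0.77 ± 0.20 and ACAT2 at -0.77 ± 0.21.

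Among liver and stem cell genes, limma called 0 of the 11 pluripotency factors, 16 oncofetal and progenitor genes and 14 mature hepatocyte genes in the filtered fit, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 1 and 2. AFP, the fetal liver secretory protein, was near the floor at 15 ± 0.66 and 13.5 ± 3.76 (SD, n = 3 each). GPC3, a fetal liver proteoglycan, was at 155 ± 18.1 and 144 ± 21.8, a log2 difference of -0.11 ± 0.20 (SE). LIN28B, an inhibitor of let-7 maturation, was at 376 ± 50.2 and 501 ± 96.4 (0.40 ± 0.21). MYC was at 564 ± 64.2 and 412 ± 114 (-0.49 ± 0.23) and TBX3 at -0.49 ± 0.21. From the other lists, SPP1 was at -0.65 ± 0.29, SOX4 at 0.47 ± 0.22, AMBP at 0.53 ± 0.23 and SLC10A1 at -0.46 ± 0.27.

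In growth, death and stress lists, single genes passed. SESN1, a stress-induced regulator of mTORC1, rose by 0.96 ± 0.19 (SE), and the other 23 of the 24 p53 target genes did not pass; 1 rose and 1 fell when adjusted over the list alone (1 passed in the unfiltered fit). CDKN1A, the CDK inhibitor p21, was at 74.4 ± 8.79 and 96.7 ± 11.6 (SD, n = 3 each), a log2 difference of 0.38 ± 0.19. Limma called 0 of 22 pro-apoptotic genes (4 at an unadjusted p under 0.05; CASP6 0.92 ± 0.26), 0 of 8 anti-apoptotic genes (2; XIAP -0.54 ± 0.21) and 0 of 12 CDK inhibitor and senescence genes (1; GLB1 0.54 ± 0.18), also adjusted over each list alone, except that 1 senescence gene passed over its list in the unfiltered fit. Of 30 ER stress and amino acid response genes, the mTORC1 inhibitor gene DDIT4 rose (1.23 ± 0.27), the tryptophanyl-tRNA synthetase gene WARS1 fell (-1.09 ± 0.17) and 28 did not pass. Adjusted over the list alone, 2 rose and 1 fell (5 passed in the unfiltered fit). Of 31 hypoxia and glycolysis genes, ADM, a vasodilator peptide gene, rose (0.90 ± 0.19), P4HA1, a collagen prolyl hydroxylase gene, fell (-1.22 ± 0.24) and 29 did not pass, with 3 higher and 1 lower adjusted over the list alone (4 passed in the unfiltered fit). SESN1, DDIT4 and ADM passed in no fit that left out 1 array, with adjusted p from 0.0508 to 0.124, P4HA1 passed only without knockdown replicate 1, and WARS1 lost the call without scrambled replicate 1 or 2 (0.0508 and 0.059).

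Of 20 TGF-beta and BMP response genes, the ligand gene TGFB2 rose (0.86 ± 0.19, SE), ID3, a BMP-induced repressor, fell (-0.93 ± 0.19) and 18 did not pass; the same number passed adjusted over the list alone. Both lost the call without any 1 array, with adjusted p from 0.0636 to 0.137. Limma called 0 of 23 PI3K-AKT components (3 at an unadjusted p under 0.05; FOXO4 0.73 ± 0.24), 0 of 18 Wnt targets (3; DKK1 -0.60 ± 0.23), 0 of 16 Notch genes (2; DLL3 -0.43 ± 0.19) and 0 of 11 NF-kB and inflammatory genes (1, NFKB2 at 0.45 ± 0.20; TNFAIP3, at 0.52 ± 0.31, was not under it). The same held adjusted over each list alone, except that 2 Notch genes passed over their list in the unfiltered fit. Of 13 Polycomb genes 0 passed (2 at an unadjusted p under 0.05) and 1 rose adjusted over the list alone (PCGF1, 0.79 ± 0.21), against 0 in the unfiltered fit. Of 12 small RNA pathway genes 0 passed (4) and 1 fell adjusted over the list alone (AGO2, -0.84 ± 0.20), against 3 called in the unfiltered fit.

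Limma called 0 of 11 genes of the DNA methylation machinery (2 at an unadjusted p under 0.05; TET1 0.63 ± 0.22, SE), 0 of 23 HOX genes (5; HOXC10 0.79 ± 0.21), 0 of 51 subunits of complex I and ATP synthase (2; ATP5IF1 0.82 ± 0.25) and 0 of 44 replication-dependent histone genes (5; H3C7 0.89 ± 0.27), also adjusted over each list alone. Of 390 genes with ZNF symbols in the filtered fit, 5 rose, among them ZNF799 (1.31 ± 0.23), ZNF442 (1.19 ± 0.19) and ZNF542P (1.11 ± 0.20), 2 fell, among them ZNF239 (-1.06 ± 0.21), and 383 did not pass. Adjusted over the list alone, 5 rose and 3 fell (0 passed in the unfiltered fit). Of the 6 fits without 1 array, ZNF442 passed in 4, ZNF799 in 2, ZNF542P in 1 and ZNF239 in 0 (adjusted p 0.063 to 0.109). In 5 lists the median had another sign than the mean and the camera direction: ER stress (median 0.083, mean -0.0172), PI3K-AKT (-0.000518 and 0.0535), TGF-beta and BMP (-0.0124 and 0.0133), HOX (-0.00384 and 0.00697) and complex I (-0.00362 and 0.031).

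Of 21 interferon response genes, IFIT3 fell from 41.6 ± 5.17 to 16.2 ± 2.08 (SD, n = 3 each), a log2 change of -1.37 ± 0.19 (SE), and 20 did not pass; 1 rose and 3 fell adjusted over the list alone (1 passed in the unfiltered fit). IFIT3 passed in each fit without 1 array. Of 24 mesenchymal genes ACTA2, smooth muscle actin, fell from 330 ± 31.6 to 163 ± 10.7, and 23 did not pass; it was also the 1 call over the list alone. It passed in no fit that left out 1 array (adjusted p 0.0508 to 0.0815). Limma called 0 of 13 epithelial genes (2 at an unadjusted p under 0.05; KRT8 0.64 ± 0.29), also adjusted over the list alone.

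Marker lists of other cell types did not pass camera. The adjusted p was 0.908 for 17 blood cell markers, 0.933 for 11 endothelial markers, 0.908 for 12 fibroblast and stellate markers and 0.908 for 7 cholangiocyte markers. Of the fibroblast markers the proteoglycan gene DCN fell from 195 ± 17.2 to 83.4 ± 21.1 (SD, n = 3 each; limma adjusted p 0.0218), also adjusted over the list alone, and 8 did not pass. DCN kept the call only without knockdown replicate 3 when 1 array was left out. Limma called 0 of the 8 blood cell, 2 endothelial and 5 cholangiocyte markers in the filtered fit, with 0 at an unadjusted p under 0.05. CD68 was at 0.40 ± 0.25 (SE), ROBO4 at 0.24 ± 0.22 and KRT7 at -0.37 ± 0.21.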

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

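Probe sets that have no single gene name here enter no gene or list above, apart from the count of 10 calls among all probe sets. One of them was higher in the knockdown. Among 6097 such probe sets in a filtered limma fit of all 20316 probe sets, 1 was higher and 5 were lower at an adjusted p under 0.05. The higher one, probe set 7972979, had a log2 fold change of 1.80, and 2 of the lower ones, 7893872 and 7896569, had -2.92 and -2.20, each with a limma adjusted p of 0.0411. These were chosen after their values were seen, and no explanation was tested.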

How the results depend on the processing

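Under the planned choices and those added after seeing the data, no called result reversed. Uncalled lists did change direction, such as Polycomb genes with quantile normalization (adjusted p 0.935), as did the uncalled genes GPC3 and ROBO4 without scrambled replicate 3 and knockdown replicate 2. The unfiltered count of 0 genes, also at 1.5-fold, became 220 at log2 5, 531 at log2 7, 58 with trend and robust settings and 40 without the genes at the floor on all arrays. Prior degrees of freedom there were 8.01, 9.13, 4.32 and 4.97 in place of 1.09; median centring raised them to 3.37 with 0 calls (2857 genes at an unadjusted limma p under 0.05). SALL4 stayed at -1.30 there, with adjusted p of 0.0112, 0.0024, 0.0331 and 0.0375. The filtered count of 220 became 531 at log2 7 (162 shared), 500 with trend and robust settings (220 shared), 33 against a 1.2-fold null with limma's treat, 10 with all probe sets, 39 to 103 without 1 array and 15 without scrambled replicate 3 and knockdown replicate 2 (11 shared), where SALL4 was at -1.20 (adjusted p 0.0737). Fewer arrays leave fewer degrees of freedom; the cause was not tested otherwise. Median centring (241), quantile normalization (242), the mean of probe sets (218) and array weights (262) stayed within 1.5 times. All 220 kept their sign in these 4. They also kept it without any 1 array, but leaving out arrays could not reverse them, since the groups of all 220 did not overlap. Replicate numbers were not taken to pair the samples. With the replicate number as a block the filtered count was 41, the unfiltered 0. The 3 called lists became 0 with an estimated correlation and 5 with fry: cholesterol synthesis, hypoxia and glycolysis, p53 targets, pro-apoptotic and ribosomal protein genes. Without scrambled replicate 3 and knockdown replicate 2 they were replication, ribosomal and NuRD genes (NuRD 0.0353; 0.0537 to 0.509 without 1 array). The adjusted p of replication was 0.39 (estimated) and 0.0686 (fry) and of ribosomal proteins 0.344 (estimated). That of mitosis was 0.123 (log2 5), 0.139 (log2 7), 0.0571 (median centring), 0.0769 (replicate block), 0.0861 (no genes at the floor), 0.0672 (both arrays left out), 0.712 (estimated), 0.29 (fry) and 0.00432 to 0.367 without 1 array; the cause was not tested. Of named gene values in the filtered fit 1012 kept their side of the threshold, 20 passed it and 162 lost it. Only genes called in that fit could lose a call, and the 1012 include uncalled genes that stayed uncalled. Genes near the floor of 10 are limited by signal: their changes are understated.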

Other observations

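The lysosomal and small nucleolar RNA lists and the patterns below were chosen after the data were seen; of their tests, both on chromosome neighbours were also worded or given their final criterion after a result was known. Lysosomal genes were higher in the knockdown. Of 69 measured, 58 had a positive and 11 a negative change, with a median log2 change of 0.23 and a camera adjusted p of 3.17e-09 (adjusted p = 0.028 with an estimated correlation, over 4 lists). In the filtered fit 8 rose and 60 did not pass, and 16 rose when adjusted over the list alone (24 passed in the unfiltered fit). Beside NPC2 these were the thioesterase gene PPT1 (340 to 830, log2 change 1.28), the thiol reductase gene IFI30 (76.3 to 181, 1.24), the sialidase gene NEU1 (1.12), the sialic acid transporter gene SLC17A5 (293 to 586), the membrane protein gene CD63 (1452 to 2816, 0.95), TMEM59 (0.93) and the cathepsin gene CTSL (765 to 1384, 0.86).

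Some small nucleolar RNAs, a class that guides modification of ribosomal RNA, fell. Of 61 box H/ACA genes 42 had a negative and 17 a positive change, with a camera adjusted p of 0.00516 (adjusted p = 0.11 with an estimated correlation), and SNORA7B, SNORA6 and SNORA14B fell. Of 112 box C/D genes 52 had a negative and 30 a positive change, with a median of 0, percentile 50 of matched lists, and a camera adjusted p of 0.0231 (adjusted p = 0.16 with an estimated correlation). In the 56 bright enough for the filtered fit the median was -0.46 and 4 fell, among them SNORD116-21 (178 to 54.5) and SNORD15A (161 to 46.2). ZNHIT6, an assembly factor of box C/D ribonucleoproteins, rose by 1.82 on the log2 scale, and a link to these falls was not tested. Of 179 microRNA host probe sets the adjusted p was 0.295 over all genes. The 54 in the filtered fit gave 0.00952, higher (adjusted p = 0.06 with an estimated correlation), and 53 of them did not pass.

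For the lysosomal genes, a brightness-dependent scaling or 1 deviating array were weighed against a shared rise with SALL4 knockdown. Without the 8 called members the median of 61 genes was 0.20, at percentile 99.98 of 10000 lists matched on expression (95% of them between -0.083 and 0.12), and camera gave p = 4.59e-06 (p = 0.0101 with an estimated correlation). The whole list, called members included, was also fitted 7 times without 1 array, or without scrambled replicate 3 and knockdown replicate 2 together. The highest camera p was 3.88e-06. The list without its called members was not fitted with arrays left out. Neither technical explanation accounts for these values, so a shared rise may be real, as a hypothesis found and tested on the same arrays. A difference in cell density or medium between the cultures stays open, since the labels give neither. An effect of the hairpin other than on SALL4 stays open too.

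For the lower ribosomal protein and replication genes the same 2 technical explanations were weighed. Both list medians lay at percentile 0 of their 10000 matched lists, which spanned -0.051 to 0.13 and -0.11 to 0.14 in 95% of cases. The highest camera p in the 7 fits with arrays left out was 2.71e-05 for ribosomal proteins and 0.000397 for replication. A lower growth rate in the knockdown cultures is a candidate explanation that was not tested. Both camera calls end in the setting that estimates the correlation between genes (adjusted p 0.34 and 0.39). The estimates were 0.015 and 0.03, against the preset 0.01. For cholesterol synthesis the estimate was -0.022, below the preset, yet the unadjusted camera p also rose, from 0.0155 to 0.058. So a higher p did not require a higher correlation, and the loss of these calls cannot be put down to correlation between genes alone.

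Genes called in the filtered fit lay next to one another more often than chance: 7 adjacent pairs changed in the same direction, where 10000 shuffles of the calls among 13691 placed genes gave 1.94 on average (one-sided permutation p 0.0033). Adjacent means consecutive among these placed genes of the filtered fit, so genes outside it can lie between the members of a pair. The pairs were ZNHIT6 and ODF2L, and ZNF442 and ZNF799, all higher, and EXTL2 and SLC30A7, TTC21B and B3GALT1, NEMP2 and NAB1, GSTA4 and CILK1, and RERGL and PIK3C2G, all lower. A copy-number difference between the cultures could give such pairs and would move uncalled neighbours too. Uncalled genes within 3 places of any called gene moved in the direction of the call by a median of 0.034, percentile 100 of the shuffles (95% between -0.028 and 0.017). These are neighbours of all called genes, so the median does not test the pairs themselves. That met the bound set for the test, but a shift this small beside the smallest called change of 0.791 leaves copy number and local regulation open, and that size criterion was added after the value was known; ZNF442 and ZNF799 are also paralogs whose probes can share signal.

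The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The filtered fit called 220 genes in the real split and at most 0 in the others, so 1 of the 10 splits gave as many. All splits used the genes filtered on the real group means, which admits genes bright in only 1 real group. The splits were thus not compared on equal terms. The unfiltered limma fit called 0 in the real split and at most 0 in the others, at any fold and at 1.5-fold, so all 10 gave as many, with 2864 genes at an unadjusted p under 0.05 in the real split. Camera called 3 lists in the real split and at most 3 in the others, in 2 of the 10; the other was the split that joins scrambled replicates 1 and 2 with knockdown replicate 2. Joining these with knockdown replicate 1 gave 1 list and with knockdown replicate 3 gave 2, and the remaining 6 splits gave 0.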
